A study of Lasiodiplodia hormozganensis with 6 samples.

How the data were processed

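RNA from mycelium of the fungus Lasiodiplodia hormozganensis, strain CBS 339.90, was sequenced at 2 growth temperatures, 25 °C and 37 °C, with 3 libraries each, all from material of 4 days of age. Per the labels' protocols, libraries were made with the QuantSeq 3' kit, which makes tags near the 3' end of polyadenylated RNA, and were read from a single end. Reads were handled with FastQC 0.11.5, cutadapt 1.11, STAR and RSEM, per the submitters' processing notes, which give no role or order. The versions of STAR and RSEM, the genome assembly, the gene annotation and the strand setting were not given in the sources used here.

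Each library had its own table of 12658 gene models. Per the file headers, the authors deposited RSEM expected counts, TPM, FPKM, a length and an effective length for each gene model. The deposited expected counts are estimated read numbers, not normalized, in which a read that matches several models is divided among them. Between 137 and 196 gene models per library had a value that was not whole, with a tolerance of 0.001. The deposited TPM and FPKM values are scaled by effective length, which a 3' tag protocol does not call for. TPM was used only as an alternative unit, and FPKM was not used in any test. Of the lengths, 98.4% were multiples of 3, so they are called coding lengths here. Models without untranslated regions can miss tags that fall in a 3' untranslated region, so a low count is not evidence of a low transcript level. The files do not pair the IDs with gene names or products, and no coordinates were used. The gene lists prepared by product name (heat shock proteins, plant cell wall degradation and others) could therefore not be tested, and genes are described as groups.

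Total expected counts per library ran from 2126763 to 2928882. Counting variance equals the common dispersion between libraries at a mean of 40.6 counts at 25 °C and 14.1 counts at 37 °C. Of the tested models, 37.6% lay below the first value at 25 °C and 8.82% below the second at 37 °C, and for these counting error was the larger term. Intervals and floors cover at most counting error, with reads taken as independent. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that. The floor was 3 counts per library.

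Expected counts were rounded to whole numbers. Models with low counts were removed with filterByExpr, which left 7867 models holding at least 99.4% of the counts of every library. The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling, robust dispersion estimates and the two-sided quasi-likelihood test of 37 °C against 25 °C. Adjusted p-values are Benjamini-Hochberg values over all tested models, with a threshold of 0.05. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM values are rounded counts relative to the total of each library. Single values per library were compared with an exact two-sided permutation test over the 20 assignments of labels, whose smallest p is 0.10. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. No 2 libraries agreed within sampling noise.

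Gene IDs carry a running number, and the transcript numbers rise with it in 100% of successive models. A run was defined as 3 or more tested models in succession along this numbering, all past the threshold, all changed at least 2-fold and all in one direction. The number of runs was compared with 10000 random orders of the tested models (one-sided permutation test, smallest p 1e-04). Adjacent numbers are described as neighbours in the numbering, not as neighbours in the genome. Classes of models (quartiles of coding length, quartiles of mean CPM over all libraries, and the 100 most abundant models) were compared with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. The bounds of these classes were set after the data had been examined.

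Choices made before the data were examined were the main test, the run definition, the alternatives listed next and the naming rule. By that rule, the 2 rising and the 2 falling models with the largest change are named, among those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. Alternatives were DESeq2 size factors, library totals alone, upper-quartile scaling, no filter, a minimum of 10 counts in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, unrounded counts, non-robust estimates, and leaving out each library in turn. Leaving out the members of the longest run, the alternatives for the class medians, all settings for the runs other than their length, adjacency, fold threshold and left-out libraries, and the class counts without each library were added after the data had been seen.

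The procedure was tested on simulated data drawn from the means, library sizes and dispersions of the 7867 models, with 50 models changed at each of 4 fold sizes. Both groups were drawn with the same dispersion for each model, and far fewer models were changed than were called in the data. The simulation therefore does not cover the wider spread at 37 °C. For 37 °C against 25 °C it recovered 44% of the planted 2-fold changes, 84% of 4-fold, 96% of 8-fold and 92% of 16-fold changes, with 6 false calls among 164. For the same comparison, on simulated calls for 7867 models, the run test gave a permutation p of 0.84 with no run planted and of 0.0058 with 15 planted runs of 4 models.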

Results

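The transcriptome of L. hormozganensis mycelium was compared between 25 °C and 37 °C, to characterise differential expression at the 2 growth temperatures in a fungus described by its submitters as a cross-kingdom pathogen. Of 12658 gene models, 1063 had no count in any library. The 3 libraries at 25 °C held 2928882, 2302769 and 2295482 expected counts for replicates 1, 2 and 3. The 3 libraries at 37 °C held 2577369, 2126763 and 2465804. The first principal component of log2 CPM took 70.7% of the variance and separated the temperatures. Pearson correlations of log2 CPM across genes were 0.967 to 0.977 within 25 °C, 0.948 to 0.953 within 37 °C and 0.836 to 0.874 between temperatures.

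The comparison of 37 °C with 25 °C called 31% of the tested gene models changed. At 37 °C, 1311 of 7867 models were higher (16.7%) and 1128 were lower (14.3%), while 5428 did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p at or under 0.05). At least a 2-fold change was seen for 882 higher and 587 lower models, and at least an 8-fold change for 147 higher and 48 lower ones. The median change was 1.25 on the log2 scale among higher models and 1.03 among lower ones. In 1304 of the 1311 higher models and 1121 of the 1128 lower ones, the 3 libraries of one temperature did not overlap the 3 of the other. Among all tested models this held for 47.4%, against 10% for chance. The share of changed models that were higher was 53.8%, and 66.2% when the deposited TPM values were tested as log2(TPM + 1).

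**Figure D1:**
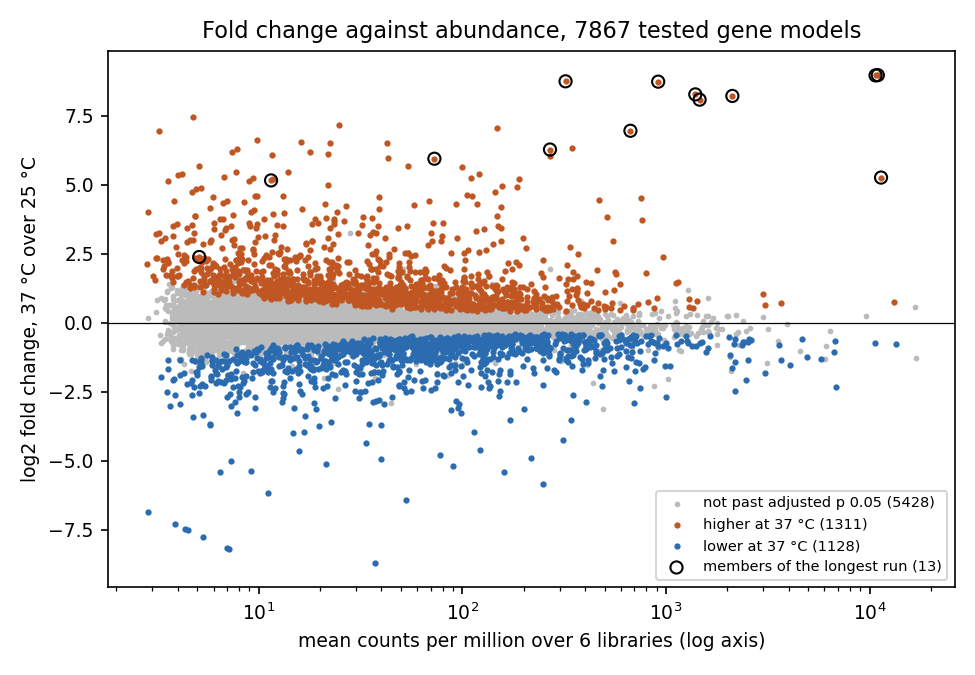
Log2 fold change (37 °C over 25 °C) against mean CPM over the 6 libraries (log axis) for the 7867 tested gene models, one point per model. The 1311 higher and 1128 lower models are coloured, and circles mark the 13 members of the longest run, which reach log2 fold changes of 8.97.

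The 2 gene models with the largest increase were gene10917 and gene10913, whose products are not given in the files. The transcript of gene10917 (coding length 867) was counted at 40.5 ± 20.5 CPM at 25 °C and 21902 ± 10022 CPM at 37 °C (SD, n = 3). Its log2 fold change was 8.97 ± 0.63 (SE, edgeR adjusted p = 0.00017). The transcript of gene10913 (coding length 603) rose from 40 ± 24.2 to 21343 ± 9956 CPM (SD, n = 3), a log2 fold change of 8.97 ± 0.74 (SE, edgeR adjusted p = 0.00048). The 37 °C libraries differed among themselves by over 2-fold for gene10917, with 47795, 70548 and 34495 counts in replicates 1, 2 and 3.

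Both models belong to a run of 13 successive tested models that were all higher at 37 °C, the longest run in the data. It spans 16 places of the gene numbering, and the 3 untested models inside it had low counts at both temperatures. Fold changes in the run ranged from 5.22 to 503 with a median of 272, and 8 of the 13 members rose at least 100-fold. The median log2 fold change was 8.09, and 6.72 as log2(TPM + 1). Each of the 13 had higher values in all 3 libraries at 37 °C than in any library at 25 °C, and adjusted p-values lay between 4.5e-08 and 0.011 (edgeR). Coding lengths ran from 603 to 6255, with 2349 for the next longest member. Together the members took 0.0676 ± 0.0137% of the counts at 25 °C and 7.99 ± 3.3% at 37 °C (SD, n = 3, exact permutation p = 0.1, the smallest possible). The 3 libraries at 37 °C gave this run 7.7%, 11.4% and 4.84% of their counts (exact 95% binomial intervals 7.67 to 7.73%, 11.4 to 11.5% and 4.81 to 4.87%). Of the 13 members, 3 stood among the 10 most abundant models of every 37 °C library. The longest run held 12 models when untested models also broke a run, with no filter, and without 25 °C replicate 1 or 2.

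**Figure D2:**
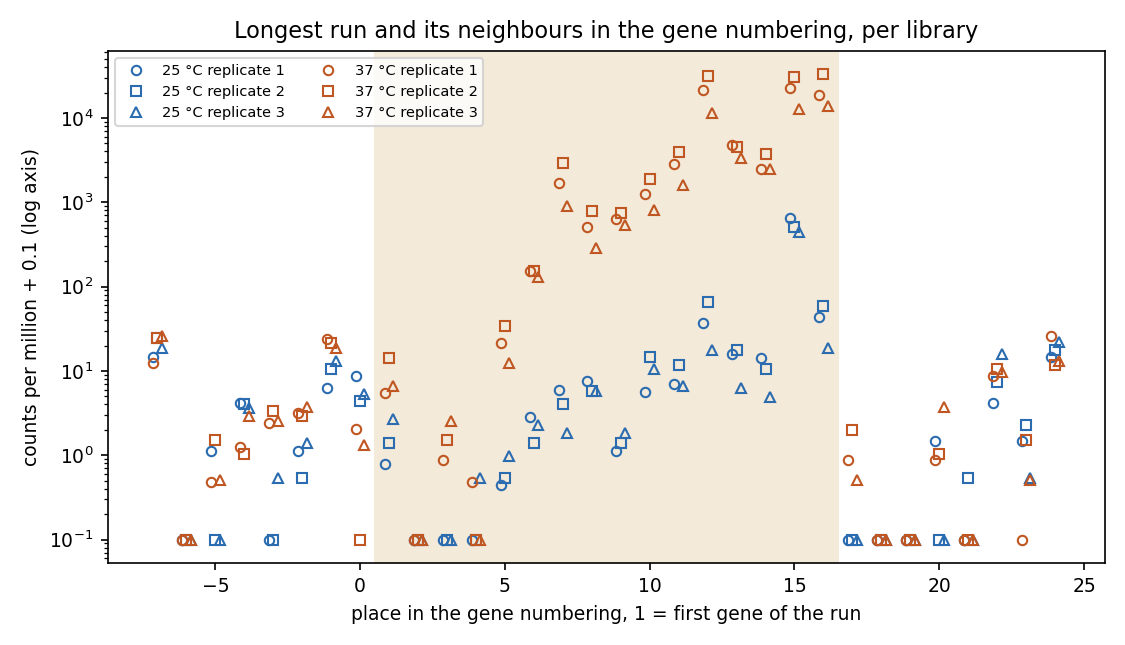
CPM plus 0.1 (log axis) in each of the 6 libraries, for the gene models of the longest run (shaded) and models before and after it, by place in the gene numbering. At 37 °C (orange) the run as a whole took 7.99% of the counts on average, against 0.0676% at 25 °C (blue). The 37 °C levels drop after the last member, but not at the left edge of the shaded block. The first member had 5.43, 14.1 and 6.49 CPM in 37 °C replicates 1, 2 and 3, while a model before the block had 23.7, 21.2 and 18.7.

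Models that changed together in this way were not limited to that block. In all, 38 runs held 136 models, or 9.26% of those changed at least 2-fold, whereas random orders of the same models gave 12.8 runs on average and at most 27 (one-sided permutation p = 1e-04, the smallest possible). Of these, 30 runs were higher at 37 °C, against a random mean of 9.82 (permutation p = 1e-04), and 8 were lower, against 3.01 (permutation p = 0.0088). The next longest runs were 2 sets of 7 models, both higher at 37 °C. One had log2 fold changes from 1.03 to 5.67 with a median of 3.63 and coding lengths of 1143 to 7503. The other had fitted log2 fold changes from 1.08 to 5.47 with a median of 3.57 and coding lengths of 858 to 1935, and the member at its upper end had 1, 1 and 0 counts at 25 °C. Another 4 runs held 4 models each and the remaining 31 held 3 each. Without 25 °C replicate 2 the number of runs was 22, with the same permutation p of 1e-04.

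**Figure D3:**
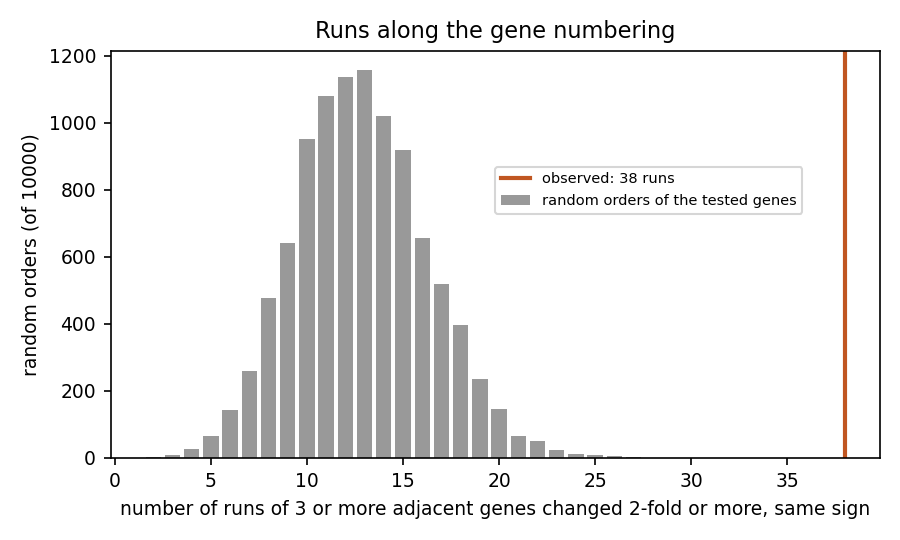
Number of runs (3 or more successive tested models, changed at least 2-fold in one direction) in 10000 random orders of the tested models (grey bars, number of orders) and in the gene numbering (orange line). The observed 38 runs lie above the highest random value of 27.

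The 2 falling models named by the rule on fitted fold change were gene5331 and gene6045, also without a named product. The transcript of gene5331 (coding length 1443) had 206, 102 and 249 counts at 25 °C and 1, 0 and 0 at 37 °C, or 74.4 ± 32.3 against 0.129 ± 0.224 CPM (SD, n = 3). Its pooled ratio of 25 °C to 37 °C was 572, with an exact 95% counting interval of 102 to 22649, and its log2 fold change was -8.71 ± 0.67 (SE, edgeR adjusted p = 3.6e-05). This fitted value was -10.55 without 37 °C replicate 1, the only 37 °C library with a count, and -5.3 as log2(TPM + 1). It stood in a run of 3 lower models with fitted log2 fold changes of -8.71 to -5.1. The transcript of gene6045 (coding length 699) had 14.3 ± 5.18 CPM at 25 °C (SD, n = 3) and no count at 37 °C. Its place in that order rests on a fitted value that depends on the prior count. Against a floor of 3 counts per library it was at least 11.4-fold lower at 37 °C (edgeR adjusted p = 0.00032).

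Transcripts counted at 1 temperature only were few. Of the models with 10 or more counts in each library of a temperature, 7 had none in the 3 libraries at 37 °C and 2 had none in the 3 libraries at 25 °C, and all 9 passed the edgeR threshold. The 7 had 11 to 59 counts per library at 25 °C and were at least 4.54-fold to at least 11.4-fold lower at 37 °C. The 2 had 11 to 31 counts and were at least 5.41-fold and at least 7.92-fold higher. The number depends on the minimum, and so does the balance, since 8 models qualified at each temperature with 5 or more counts, and 2 at 25 °C and 0 at 37 °C with 20 or more. Both also depend on single libraries. Without 25 °C replicate 1 there were 7 models at 25 °C only and 7 at 37 °C only, without 25 °C replicate 2 there were 7 and 10, without 25 °C replicate 3 there were 8 and 6, and without 37 °C replicate 1 there were 9 and 6.

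The breadth of the detected set was compared at an equal total count per library and as sequenced. With all libraries thinned to 2126760 counts, 7651 ± 112 models had 10 or more counts at 37 °C and 7263 ± 57.3 at 25 °C (SD, n = 3, exact permutation p = 0.1, the smallest possible). Without thinning the values were 7848 ± 222 and 7509 ± 232 (SD, n = 3, exact permutation p = 0.2).

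Among the 100 most abundant models, 36 were lower at 37 °C and 13 were higher, while 51 did not pass the threshold. The class median was -0.39 and its mean 0.02 on the log2 scale, so they differ in sign. Members of the longest run in this class, with log2 changes of up to 8.97, raise the mean. With that run left out the median was -0.43. The class test pointed downward, like the median, and gave no call (camera in limma, adjusted p = 0.055, and adjusted p = 0.27 with an estimated correlation). Without 25 °C replicate 2 there were 28 lower and 7 higher. Of the 10 most abundant models, 4 were higher, 3 of them in the longest run, 3 were lower and 3 did not pass. The largest change among the lower ones took a transcript from 11271 ± 654 to 2410 ± 623 CPM (SD, n = 3). The 100 most abundant models of each temperature had 72 in common, against 1.27 for independent lists drawn from the tested models. Overlap between libraries of the same temperature was not computed, so these values do not show how far the lists differ by temperature. The 10 most abundant models of each library took 12.2 ± 0.518% of the counts at 25 °C and 15 ± 2.4% at 37 °C (SD, n = 3, exact permutation p = 0.3). Without the longest run this difference turned to -1.3 percentage points (exact permutation p = 0.5).

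The tested models were also compared by abundance class. In the most abundant quartile (89.9 CPM or more), 473 were lower and 333 higher, with a median log2 change of -0.14. In the least abundant quartile (2.77 to 11.5 CPM), 145 were lower and 284 higher, with a median of 0.14. The camera adjusted p was 0.059 for the first and 0.35 for the second, so neither class passed (adjusted p = 0.27 for both with an estimated correlation). Tested as log2(TPM + 1), the median of the most abundant quartile was 0.01, with all models shifted to a median of 0.15. The 2 middle abundance quartiles held 325 higher and 184 lower models (median 0.11, camera adjusted p = 0.35) and, in the more abundant one, 369 higher and 326 lower (median -0.01, mean 0.04, camera adjusted p = 0.97). Leaving out a 25 °C library lowered these counts. The least abundant quartile held 84 lower and 173 higher models without replicate 1, 96 and 182 without replicate 2, and 109 and 186 without replicate 3. Without replicate 2 the most abundant quartile held 337 lower and 215 higher models, and the second least abundant one held 215 higher and 128 lower, or 207 and 139 without replicate 3.

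By coding length, the longest quartile of models (1917 or more) held 409 higher and 164 lower ones, with a median log2 change of 0.18. Of the shortest quartile (up to 900), 266 were higher and 387 lower, with a median of -0.15. Camera gave adjusted p = 0.055 and 0.08, so neither passed (adjusted p = 0.27 for both with an estimated correlation). In the 2 middle length quartiles, 336 were higher and 318 lower (median -0.02, mean 0.09) and, in the longer one, 300 were higher and 259 lower (median 0.03, mean 0.09). Camera, which compares a class with the other tested models and not with no change, pointed downward for both without a call (adjusted p = 0.89 and 0.97). The 25 °C replicate 1 library stood apart in coding length. The log2 differences of 25 °C replicates 2 and 3 from replicate 1 correlated with coding length across genes at 0.15 and 0.17 (Spearman), beside 0.14 for the fold change between temperatures. Without replicate 1 the counts were 253 higher and 130 lower in the longest quartile and 198 higher and 245 lower in the shortest. The longest quartile held 256 higher and 108 lower models without 25 °C replicate 2, and 257 and 106 without 25 °C replicate 3, and the second shortest held 222 and 220 without 25 °C replicate 2. Tested as log2(TPM + 1), the median of the shortest quartile was also 0.01.

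The spread among libraries was described for each temperature, without a test. The biological coefficient of variation over the tested models was 0.266 at 37 °C and 0.157 at 25 °C (edgeR common dispersion). Among the 100 models with the highest mean CPM, 72 had the larger coefficient of variation at 37 °C, with a median of 16.9% against 8.95%. These values were on CPM without TMM scaling, and the list includes members of the longest run. That run took 4.84% to 11.4% of the counts of the 37 °C libraries, which also moves the CPM of the other models.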

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

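The omission of the longest run, the alternatives for the class medians and the normalization, filter, test, unit and block settings for the runs were chosen after the results had been seen. Over 18 results and 310 alternative values, 293 met the criterion for their kind and 17 did not. The criterion was the same direction and side of the threshold for a tested value, a move within 1.5 times for a count, and for a class median the same direction and a move smaller than the median standard error of its members. The numbers of changed models stayed within 1.5 times under the 13 other settings and the 6 omissions of a library, with 896 to 1611 higher and 788 to 1185 lower models. No model called with both the main and an alternative setting changed direction. The median over all tested models was 0.01 with TMM, 0.12 with library totals alone, and 0.15 and 0.16 with log2(TPM + 1) and log2(TPM + 0.1), and the share of higher models was 53.8%, 63.3%, 66.2% and 66.4%. Under both TPM settings the median log2 changes of the shortest and of the most abundant quartile reversed to 0.01, which lies below the median of all models there. The number of runs was 7 for runs of 4 or more models (permutation p = 4e-04), 23 when untested models also broke a run and 82 with no fold threshold, by construction of these settings, and 22 to 42 with 1 library left out. The lowest of these, without 25 °C replicate 2, had a cause that was not tested. The number of models counted at 1 temperature only was 16 with a minimum of 5 counts, 2 with a minimum of 20, and 10 to 17 with 1 library left out, where fewer libraries had to meet the criteria. The difference in the share of the 10 most abundant models reversed to -0.793 percentage points for the 100 most abundant, for which the cause was not tested, and to -1.3 without the longest run. The median of the longest run was 6.72 with log2(TPM + 1), a scale that understates changes from low levels. In every alternative that held them, gene10917, gene10913, gene5331 and gene6045 kept their direction and passed, with a largest adjusted p of 0.0037, while the fitted log2 change ranged from -10.55 to -5.3 for gene5331 and from -8.42 to -4.21 for gene6045. The replicate block gave 1187 higher and 1057 lower models and 36 runs. Deviations of same-numbered libraries from their group means correlated at 0.11, 0.01 and -0.08, and 1 of the 3 libraries at 25 °C correlated best with its own number, so the numbers were not taken to pair the samples. The lists by product name and their alternatives were not run, because the files do not pair the IDs with names. Depth limits what can be said of the 4791 models below the filter.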

Other observations

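The tests on the order of neighbours, on models counted at 25 °C only, on the longest run, and on depth and single libraries in the spread were chosen after the results had been seen. Outside the longest run, adjacent tested models also changed alike more than in random orders. Their log2 fold changes correlated at 0.07 (Spearman, across genes, which are not independent replicates), above the highest of 10000 random orders, 0.04 (permutation p = 1e-04, the smallest possible). At 2 places apart the correlation was 0.01, and at 5 places 0. Of the 7 models counted at 25 °C only, 4 lay within 5 numbers of another of the 7, and 10000 random draws of 7 tested models gave at most 2 (permutation p = 1e-04, the smallest possible). No coordinates were used, so whether these models are neighbours in the genome was not tested.

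The longest run held 13 successive models with a median increase of 272-fold at 37 °C. Chance order is argued against, since the longest run in 10000 random orders was 7. Reads divided between near-identical copies would leave values that are not whole, which argues against them for the 9 of 13 members that were whole in all 6 libraries, at up to 70548 counts, and leaves them open for the other 4, which were not whole in at most 2 libraries (6.41% of the run's values, against 2.03% elsewhere). Spill-over of reads from a single neighbour needs constant ratios of adjacent members. Of 12 ratios, 11 differed between the 37 °C libraries beyond counting error (chi-square test, Benjamini-Hochberg adjusted). Sets of count-matched pairs of other models gave a median of 11 and a range of 7 to 12. The run's ratios therefore differed as often as those of other models. The highest ratio over the lowest had a median of 1.72 in the run. Count-matched pairs over the 37 °C libraries had medians of 1.52 to 2.13. These values argue against spill-over from a single neighbour for the run as a set. Only 2 of the 12 varied by more than the 95th percentile of count-matched pairs of other models over the 25 °C libraries. Pairs of other models set that bound, so a ratio below it cannot decide. Some pairs of members varied less, such as 1.14 for gene10911 and gene10912, so spill-over stays open for single pairs. Joint regulation of the members by temperature also stays open, and what these models encode was not tested.

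Fold change correlated with coding length at 0.14 across the tested models (Spearman, genes not being independent replicates), although neither the longest nor the shortest quartile passed its class test (camera adjusted p = 0.055 and 0.08, and adjusted p = 0.27 for both with an estimated correlation). A difference in abundance between short and long models is argued against, as the correlation of fold change with coding length was at least 0.11 in each abundance quartile. A length bias that varies from library to library stays open, because libraries of the same temperature reached a correlation of 0.17, within the range of the pairs of different temperature (0.07 to 0.2). That value involves 25 °C replicate 1, and without this library the 4 pairs of the same temperature lay at 0.01 to 0.05, below the 6 pairs of different temperature at 0.07 to 0.12, and the correlation of the fold change was 0.1. An effect of temperature on transcripts of different length was not tested apart from this bias.

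The wider spread among the 37 °C libraries (1.69 times that at 25 °C) was not removed by equal total counts, with a ratio of 1.73 after thinning. It did not rest on 1 library, since the closest pair at 37 °C still had a coefficient of 0.254 against 0.197 for the farthest pair at 25 °C. It did not rest on the 100 most abundant models or the longest run either, with a ratio of 1.68 without them. Biological differences between cultures at 37 °C and differences in handling stay open, as the labels give no batch.

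With 3 libraries against 3 there are 10 splits of the samples, too few for a share under 0.05. The real split, the 1 split with results as large, gave 1311 higher and 1128 lower models, 882 and 587 at 2-fold or more, and 38 runs. The highest of the other 9 splits was 0 for each of these results (edgeR), with 42 to 187 models at an unadjusted p at or under 0.05, against 3302 for the real split. Each of these 9 splits put libraries of both temperatures in both groups, so the temperature difference counted as spread there. Their counts of 0 therefore do not measure what groups without a real difference would give.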
